A study of Caulobacter vibrioides with 4 samples.

How the data were processed

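The data were RNA sequencing libraries from Caulobacter crescentus NA1000, a laboratory strain of a freshwater bacterium that divides into a flagellated swarmer cell and a stalked cell. There were 4 libraries, 2 labelled wild type (WT) and 2 labelled ΔflaF, a strain in which the flagellar regulatory gene flaF was deleted. Per the labels' protocols, the cultures were independent biological replicates grown in PYE, a rich peptone and yeast extract medium, into exponential phase. Each library was made from total RNA after depletion of ribosomal RNA, with a kit that keeps strand, and sequenced as single reads. Groups and replicate numbers came from the sample titles.

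Per the labels' protocols, the authors checked reads with FastQC 0.11.5, mapped them with BWA 0.7.15 to an NCBI reference of strain NA1000, and counted reads per gene feature with HTSeq 0.6p1. The version of that reference, the strand setting of the counter and its treatment of reads with several matches or in overlapping features are not given in the sources used here. The deposited count table held whole-number counts for 4165 features, of which 42 were 0 in all 4 libraries. The authors' second deposited table gave a scaled signal for 4024 features, named CPM in its header. In each library it equalled the counts divided by 1 constant, an effective library size that was not the column total. Its columns summed to between 916702 and 1053952, so its values were used only to check the authors' scaling. The authors' deposited comparison table gave log2 fold changes of ΔflaF over WT, with p-values and adjusted p-values, for the same 4024 features, made with edgeR 3.18.1 per the labels' protocols. The 141 features missing from the latter tables had at most 17 counts in any library.

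Gene names, products and the order of neighbouring genes came from a RefSeq gene table of assembly ASM2200v1. Of the features, 4084 matched a locus tag in it and 81 did not. Because the authors' reference version is not named, no coordinates are given. Genes without a symbol are named by locus tag.

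The total counts were 8479403 and 10050515 in WT replicates 1 and 2, and 10206524 and 10864552 in ΔflaF replicates 1 and 2. Ribosomal RNA took 0.0096 to 0.0144% of the counts. The S-layer gene rsaA took the largest share, 8.15 to 9.33%. RNase P RNA took 0.347% of the counts in WT replicate 1 and 1.242, 1.108 and 1.159% in WT replicate 2 and ΔflaF replicates 1 and 2. Replicates differed by more than sampling noise. The chi-square per degree of freedom was 57.7 between the WT libraries and 8.18 between the ΔflaF libraries, over features with at least 20 counts, so each library was counted as 1 sample. Against ΔflaF replicates 1 and 2 it was 44.5 and 43.0 for WT replicate 2, and 101 and 93.8 for WT replicate 1, so WT replicate 2 was closer to the ΔflaF libraries than to the other WT library.

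The counts as deposited were tested with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), without a term for replicate number. Features were filtered with filterByExpr, which removed 151 and left 4014, and libraries were scaled with trimmed mean of M-values (TMM) factors. The test was two-sided, and adjusted p-values are Benjamini-Hochberg values over the features tested, with 0.05 as the threshold. The verbs rose and fell refer to genes past this threshold. CPM values are counts scaled to a common total by the TMM-scaled library size, given as mean ± SD with n = 2 per group. A standard error (SE) was obtained from the fold change and the test statistic. With 2 libraries against 2, a permutation of library labels cannot give a two-sided p below 0.333, so p-values rest on the model.

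Before the data were examined, 24 gene lists were fixed from known symbols and product descriptions, and 24 had enough members to be tested. They covered flagellins, flagellar secretion and basal body, hook and junction, flagellin modification, motor and chemotaxis, type IV pili, holdfast, stalk, cell cycle regulators, G1 swarmer and S phase genes, cell division, c-di-GMP enzymes, ribosomal proteins, heat shock, SOS repair, oxidative stress, phosphate, iron, TonB-dependent receptors, S-layer and capsule, mobile elements, toxin-antitoxin pairs and respiration. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, then with an estimated correlation and with fry. The rule for named genes was also fixed then. It took flaF, flbT and the 6 flagellins, the 8 protein-coding genes with the greatest rise and the 8 with the greatest fall among those past the threshold with no overlap between groups, up to 4 members past the threshold from each list, and 5 neighbours on each side of flaF. Genes named outside this rule are said to have been chosen after their values were seen, as were rsaA and RNase P RNA.

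The test was checked on simulated counts for the 4014 features of this comparison, with 50 genes changed at each of 4 fold sizes. Gene dispersions were drawn around the fitted trend with the gene-to-gene spread estimated from the libraries, since shrunken estimates varied less between genes than the libraries did. The test recovered 50% of 1.5-fold, 96% of 2-fold, 98% of 4-fold and 100% of 8-fold changes, and 15 unchanged genes were called, 8.02% of the calls. That share depends on how many genes were changed, and the simulated genes varied independently of each other. It is therefore not the error rate of the calls reported here. Each simulated gene had the same dispersion in both groups. The WT libraries differed more from each other (SD of the log2 difference 0.31) than the ΔflaF libraries did (0.18). The recovery in the libraries may therefore differ from that in simulation. This simulation replaced a first one, drawn from the shrunken estimates, after its results were seen. The first recovered 80% of 1.5-fold, 94% of 2-fold and 100% of 4-fold and 8-fold changes, with 19 unchanged genes called, 9.22% of its calls. In a further simulation camera called a list of 20 genes raised 1.5-fold and 0 of 20 unchanged lists at the preset correlation, and did not call the raised list with an estimated correlation. The simulated genes varied independently, so this does not check camera on lists whose members vary together. In the libraries the estimated correlation was 0.87 for ribosomal proteins and 0.79 for flagellins. With it camera gave the flagellins an adjusted p of 0.624, though all 6 passed the threshold as single genes. A miss with an estimated correlation therefore does not decide against a list.

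Alternatives fixed before the data were examined were other scalings (DESeq2 size factors, library size only, upper quartile), other tests (DESeq2 1.42.0, the edgeR exact test, limma-voom, glmTreat against 1.5-fold), other filters, a replicate block, leaving out each library, removal of rRNA and tRNA features, and an adjusted p below 0.01.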

Results

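RNA was measured in 2 WT and 2 ΔflaF cultures of Caulobacter crescentus NA1000, with total counts of 8479403 to 10864552 per library. The study's title concerns control of flagellins, the proteins that polymerise into the flagellar filament, by an unusual flagellin paralog. The comparison of ΔflaF with WT asks which messages differ in cells labelled as lacking flaF, a gene known in flagellated bacteria as a regulator of flagellin production.

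Reads were still counted in flaF in both libraries labelled ΔflaF. The level of flaF was 125 ± 27.9 CPM in WT and 82.3 ± 4.81 CPM in ΔflaF (SD, n = 2 each). Its log2 fold change was -0.60 (SE 0.15), with an adjusted p of 0.103 by edgeR's quasi-likelihood test, and -0.61 with an adjusted p of 0.0531 in the authors' deposited table. The ΔflaF level was 66.0% of the WT level, and 54.6 to 81.7% over the pairs of libraries. Of flaF, the tables hold 1 count per library, and the extent of the deletion is not given in the sources used here. In the RefSeq gene table flaF overlaps flbT, so reads in the shared part are uncertain. The flaF values therefore do not check the genotype, and each direction below refers to the libraries labelled ΔflaF. The call for flaF depended on the test and on the libraries used, and the size of its change on the libraries. Its adjusted p was 0.0341 with DESeq2 and 0.0094 with the edgeR exact test. It was 0.0644 with DESeq2 size factors, 0.283 with library size scaling, 0.171 with upper-quartile scaling, 0.112 with limma-voom and 0.136 with the filter at a CPM of 10. The log2 fold change was -0.81 and -0.37 without WT replicates 1 and 2, and -0.66 and -0.54 without ΔflaF replicates 1 and 2.

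The flagellin messages split in opposite directions. In the libraries labelled ΔflaF, fljL rose from 3369 ± 542 to 13279 ± 721 CPM, while fljK, fljM, fljN and fljO fell to small fractions of their WT levels. The message of fljK fell from 2101 ± 197 to 256.5 ± 1.21 CPM, and that of fljM from 3089 ± 247 to 431 ± 38.1 CPM. The message of fljN fell from 1106 ± 183 to 128 ± 24.2 CPM and that of fljO from 86.5 ± 12.7 to 12.2 ± 0.178 CPM. The smaller change of fljJ was from 405 ± 25.9 to 256 ± 4.40 CPM (SD, n = 2 in each group for all 6 genes).

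By edgeR's quasi-likelihood test all 6 flagellins passed the threshold, 1 higher and 5 lower, and the same counts were obtained adjusted over the list alone. The log2 fold change of fljL was 1.98 (SE 0.25, adjusted p 0.0039). Those of fljN, fljK, fljM and fljO were -3.11, -3.03, -2.84 and -2.82 (SE 0.18, 0.16, 0.17 and 0.14), with adjusted p-values of 2.2e-05, 1.3e-05, 2.2e-05 and 1.3e-05. For fljJ the log2 fold change was -0.66 (SE 0.11, adjusted p 0.0192). Together the 6 genes had 10156 ± 1207 CPM in WT and 14363 ± 780 CPM in ΔflaF, and fljL made up 33.1% of flagellin CPM in WT and 92.5% in ΔflaF. The flagellins are paralogs, and how the counting divided reads shared between them is not given in the sources used here, so single flagellin levels are uncertain to that extent. Without ΔflaF replicate 1, fljL missed the threshold (log2 fold change 1.92, adjusted p 0.0711), and fljJ missed it without ΔflaF replicate 1 (adjusted p 0.231), without ΔflaF replicate 2 (0.157) and with library size scaling (0.0812).

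**Figure D1:**
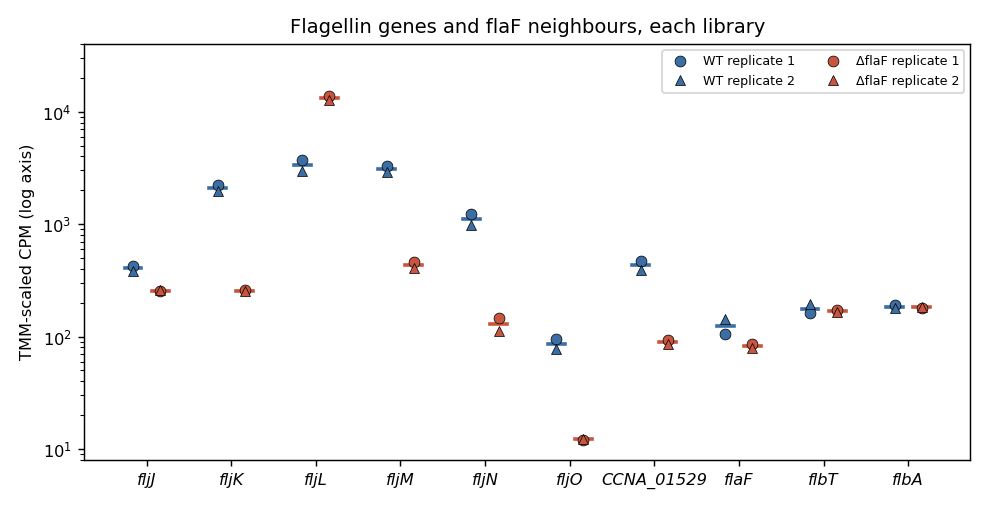
TMM-scaled CPM (log axis) of the 6 flagellin genes, CCNA_01529, flaF, flbT and flbA in each library, with bars at group means of 2 libraries. The ΔflaF libraries lie above WT for fljL (mean 13279 against 3369 CPM) and below it for the other flagellins, while flaF keeps 82.3 CPM.

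The genes around flaF changed on the fljL side. Of the 10 neighbours, 5 on each side, fljL rose and fljK, CCNA_01529 and fljJ fell, all on the same side of flaF. Of these, fljL, fljK and fljJ are flagellins. The flagellins fljM, fljN and fljO, which are not among the 10, had log2 fold changes of -2.84, -3.11 and -2.82, against -3.03 for fljK. CCNA_01529, annotated as a FlaG superfamily protein, fell from 433 ± 54.4 to 89.1 ± 4.66 CPM (SD, n = 2 each), a log2 fold change of -2.28 (SE 0.12, adjusted p 1.3e-05, edgeR's quasi-likelihood test). The adjacent flbT, known as a regulator of flagellin translation, had 177 ± 22.9 CPM in WT and 169 ± 4.74 CPM in ΔflaF, a log2 fold change of -0.06 (SE 0.11, adjusted p 0.825). The fifth gene on the fljL side, CCNA_01531, had a log2 fold change of -0.41 and missed the threshold (adjusted p 0.122), which it passed with the edgeR exact test (0.0313) and without WT replicate 2 (3.5e-04). On the other side flbA, flmH, CCNA_01522 and CCNA_01521 had log2 fold changes of -0.02, 0.07, 0.01 and -0.07, none past the threshold. Without ΔflaF replicate 1 the number past the threshold was 2 of the 10. Without WT replicate 2, flmH passed it at a log2 fold change of 0.52 (adjusted p 0.0014).

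Across the transcriptome 62 of 4014 tested features passed the threshold, 22 higher and 40 lower in the libraries labelled ΔflaF. Among protein-coding genes the greatest falls after the flagellins were in CCNA_00438, a hypothetical protein, from 1243 ± 199 to 214 ± 8.61 CPM, in CCNA_01529, and in the hypothetical protein CCNA_02061, from 129 ± 1.89 to 48.2 ± 3.55 CPM. The greatest rise after fljL was in nstA, from 74.4 ± 8.20 to 237.5 ± 21.6 CPM. The TonB-dependent receptors CCNA_00185 and CCNA_01170 rose from 28.3 ± 2.44 to 54.5 ± 1.05 CPM and from 90.2 ± 5.73 to 171 ± 7.80 CPM (SD, n = 2 in each group).

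The log2 fold changes were -2.54 for CCNA_00438 (SE 0.16, adjusted p 2.2e-05), -1.42 for CCNA_02061 (SE 0.10, adjusted p 8.2e-05) and 1.67 for nstA (SE 0.12, adjusted p 6.7e-05), by edgeR's quasi-likelihood test. CCNA_00185 had 0.94 (adjusted p 0.0028) and CCNA_01170 had 0.92 (adjusted p 0.0017). Smaller rises were those of CCNA_03208 (0.89), annotated as a steroid 5-alpha reductase family enzyme, the nitrite reductase subunit nirB (0.81), the acyl-CoA dehydrogenase CCNA_01167 (0.77) and the hypothetical protein CCNA_01169 (0.75). With library size scaling these 4 rises missed the threshold, with adjusted p-values of 0.0807, 0.139, 0.0888 and 0.139. Both nirB and CCNA_01169 also missed it with upper-quartile scaling (0.0652 each), limma-voom (0.0573 and 0.0560), the filter at a CPM of 10 (0.0593 each) and without ΔflaF replicate 2 (0.297 and 0.292), and CCNA_01167 missed it without ΔflaF replicate 1 (0.134) or ΔflaF replicate 2 (0.166). Of the 62 features, 59 were protein coding. The 3 noncoding ones, chosen after their values were seen, were CCNA_R0017 (-2.47) and CCNA_R0176 (-1.86), which fell, and CCNA_R0180 (0.60), which rose. The call for CCNA_R0180 ended with library size scaling (adjusted p 0.140), upper-quartile scaling (0.0652), DESeq2 (0.0523), limma-voom (0.0582), the filter at a CPM of 10 (0.0593) and without ΔflaF replicate 1 (0.134). Of the 62, 15 changed by at least 1 on the log2 scale, 2 higher and 13 lower. The groups did not overlap in CPM for any of the 62, which was also the case for 49.1% of all tested features, against 33.3% by chance. The authors' deposited table called 90 features at an adjusted p below 0.05, 40 higher and 50 lower, of which 61 were among the 62. Its log2 fold changes correlated with those of the present fit across genes (r = 1.00, 4014 genes, which are not independent replicates). Both fits used edgeR on the same libraries, so this match was nearly fixed in advance and lends the calls no support. At an unadjusted p below 0.05 there were 549 features. The count was 25 with library size scaling, which moved the median of all genes by 0.13 on the log2 scale, and 161 with the edgeR exact test. It was 119 without WT replicate 1 and 1162 without WT replicate 2, with the 62 kept in each.

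**Figure D2:**
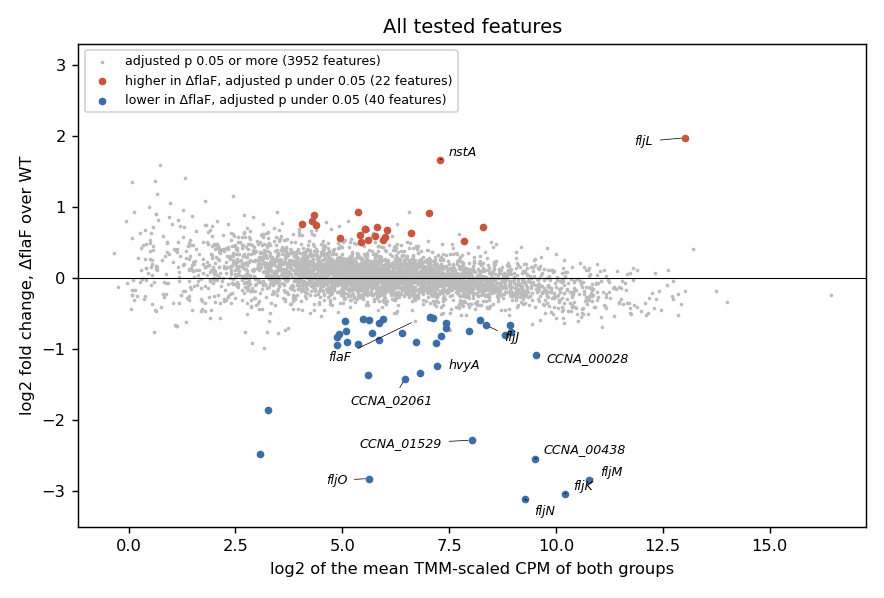
Log2 fold change of ΔflaF over WT against log2 of the mean TMM-scaled CPM for the 4014 tested features, each point 1 feature. The 22 features that rose and 40 that fell are coloured, with fljL (1.98) and nstA (1.67) highest and fljN (-3.11) lowest.

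Genes for the rest of the flagellum showed few changes. None of the 26 secretion and basal body genes passed the threshold by edgeR's quasi-likelihood test, with log2 fold changes of -0.30 to 0.12. In the hook and junction list 1 of 8 fell, CCNA_02931, annotated as a flgE-related hook protein, from 69.5 ± 10.7 to 27.2 ± 1.17 CPM (SD, n = 2 each, log2 fold change -1.36, SE 0.13, adjusted p 6.4e-04). None of the 5 flagellin modification genes and none of the 44 motor and chemotaxis genes passed, with ranges of -0.07 to 0.41 and -0.35 to 0.60. At an unadjusted p below 0.05 there were 3, 0 and 5 genes in these 3 lists, and DESeq2, the edgeR exact test and limma-voom each called 0. The same counts were obtained adjusted over the list alone. The motor and chemotaxis list found 8 of its 31 symbols and is incomplete. Outside it, CCNA_00888 and CCNA_02976, annotated as MCP-signal associated domain proteins and named after their values were seen, fell. Their log2 fold changes were -0.89 and -0.55 (adjusted p 0.0017 and 0.0291, edgeR's quasi-likelihood test). Only the call for CCNA_00888 was kept in all 14 settings of the gene test.

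By camera the secretion and basal body list was lower as a set (median -0.09, adjusted p 0.0167), which gave an adjusted p of 0.624 with an estimated correlation, and 0.319 without WT replicate 1, 0.0999 without ΔflaF replicate 1 and 0.146 with library size scaling. The median was -0.015 without WT replicate 1 and -0.16 without WT replicate 2, and its median difference between these libraries was 0.14. Camera did not call the hook, modification or motor lists (adjusted p 0.116, 0.495 and 0.309). Without WT replicate 2, which leaves WT replicate 1 alone in its group, the medians were -0.25 for hook, 0.13 for modification and 0.07 for motor genes. Without WT replicate 1 they were -0.11, 0.07 and 0.06.

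Of 4 genes known to be expressed in the newborn swarmer cell 3 fell. These were hvyA, which keeps swarmer cells from being capsulated, from 210 ± 2.44 to 89.3 ± 4.22 CPM, perP, from 106 ± 0.995 to 62.5 ± 0.601 CPM, and sciP, an inhibitor of the cell cycle regulator CtrA, from 621 ± 57.0 to 369 ± 35.8 CPM (SD, n = 2 each). The pilin gene pilA, named after its value was seen, had a log2 fold change of -0.36 and missed the threshold over all genes (adjusted p 0.246). It also missed the threshold with DESeq2 (0.160), the edgeR exact test (0.153), limma-voom (0.241) and library size scaling (0.295). Its log2 fold change was -0.35 and -0.38 without WT replicates 1 and 2, and -0.39 and -0.33 without ΔflaF replicates 1 and 2. All 4 genes were lower when adjusted over the list alone.

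The log2 fold changes were -1.23 for hvyA (SE 0.10, adjusted p 1.4e-04), -0.76 for perP (SE 0.10, adjusted p 0.0041) and -0.75 for sciP (SE 0.13, adjusted p 0.025), by edgeR's quasi-likelihood test. Camera gave the list an adjusted p of 1.2e-06, and 0.624 with an estimated correlation. The WT libraries differed in the median of this list by 0.02 on the log2 scale. None of the 9 S phase and stalked cell genes passed (median -0.0039, camera adjusted p 0.603). Of the 26 cell cycle regulators only sciP fell (camera adjusted p 0.427), and of the 30 cell division genes none passed (camera adjusted p 0.495). DESeq2, the edgeR exact test and limma-voom also called 0 S phase and 0 division genes, with 2 and 3 at an unadjusted p below 0.05. Without WT replicate 2 the medians were -0.053 for S phase, 0.024 for division and 0.0060 for regulator genes. Without WT replicate 1 they were -0.015, 0.0068 and -0.038. With library size scaling sciP and perP missed the threshold (adjusted p 0.0902 and 0.0562), and sciP also missed it without ΔflaF replicate 1 (0.103) or ΔflaF replicate 2 (0.433).

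Genes for other polar and surface structures moved in both directions. Of 15 genes for type IV pili, the retractile fibres at the swarmer pole, 3 rose, namely cpaB, from 76.8 ± 4.04 to 119 ± 0.907 CPM, cpaD, from 35.3 ± 2.96 to 56.9 ± 3.10 CPM, and cpaE, from 188 ± 18.2 to 270 ± 7.68 CPM (SD, n = 2 each). In the holdfast list, which makes the adhesive at the stalk tip, 1 of 17 fell, the glycosyltransferase gene hfsJ, from 167 ± 6.21 to 113 ± 0.413 CPM. In the stalk list 1 of 13 fell, tacA, a response regulator, from 359 ± 22.1 to 239 ± 0.108 CPM. In the S-layer and capsule list 1 of 9 fell, hvyA.

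By edgeR's quasi-likelihood test the log2 fold changes were 0.63, 0.69 and 0.52 for cpaB, cpaD and cpaE (adjusted p 0.0175, 0.0184 and 0.0497), -0.56 for hfsJ (adjusted p 0.0222) and -0.58 for tacA (adjusted p 0.0263). Adjusted over the list alone, 7 pilus genes were higher and 1 lower, and 1 gene was lower in each of the holdfast, stalk and S-layer lists. Camera called none of these lists (adjusted p 0.222, 0.533, 0.533 and 0.262). The stalk list had a median of 0.05 and a mean of -0.04. Without ΔflaF replicate 1 the calls for cpaE, hfsJ and tacA ended (adjusted p 0.174, 0.140 and 0.303), as they did without ΔflaF replicate 2 (0.319, 0.156 and 0.294). The call for cpaE also ended with DESeq2 size factors (0.0538), limma-voom (0.0560) and the filter at a CPM of 10 (0.0516). With library size scaling hfsJ and tacA missed the threshold (adjusted p 0.128 and 0.109). Without WT replicate 2 the medians were 0.12 for pilus, -0.010 for holdfast, 0.038 for stalk and -0.062 for S-layer and capsule genes. Without WT replicate 1 they were 0.055, 0.0078, -0.024 and -0.061. The number of pilus genes past the threshold was 7 in all with the edgeR exact test and 5 with library size scaling.

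**Figure D3:**
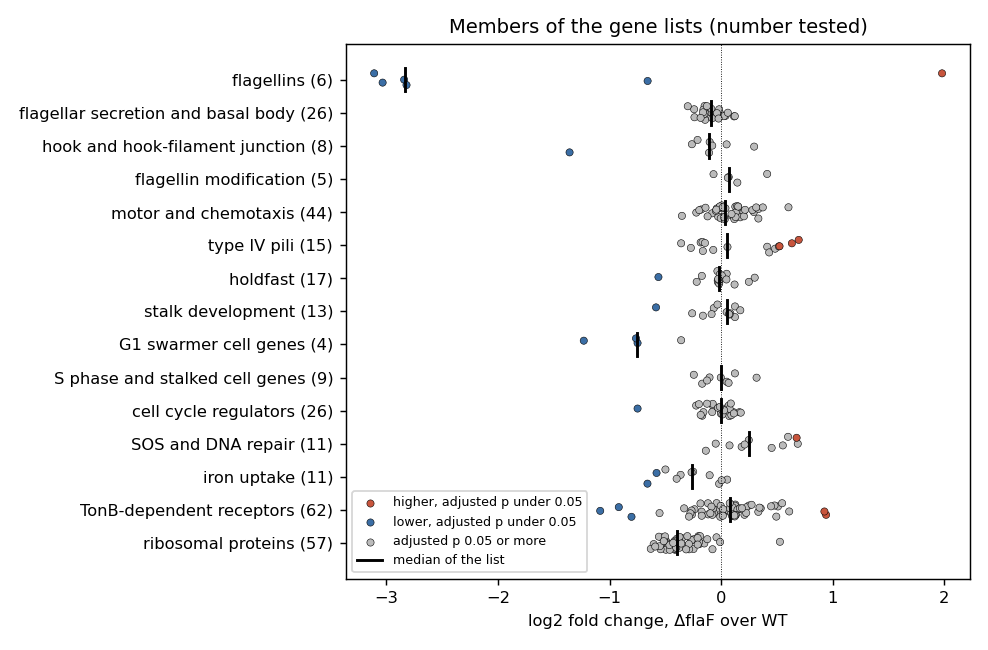
Log2 fold change of ΔflaF over WT for each tested member of 15 of the fixed gene lists, each point 1 gene, with the list's median as a black bar. Flagellins spread from -3.11 to 1.98, while the 26 secretion and basal body genes stay between -0.30 and 0.12.

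Transport genes moved in both directions. Of 62 TonB-dependent receptors, outer membrane proteins that import iron complexes and other nutrients, 2 rose (CCNA_00185 and CCNA_01170) and 3 fell. Of those that fell, CCNA_00028 went from 1005 ± 210 to 474 ± 4.42 CPM and CCNA_00138 from 192 ± 0.939 to 102 ± 10.2 CPM. The ferrous iron transport genes CCNA_00748 and CCNA_00749 fell from 53.7 ± 5.49 to 35.8 ± 0.255 CPM and from 594 ± 74.2 to 375 ± 24.5 CPM (SD, n = 2 each), 2 of the 11 iron uptake genes. None of the 10 phosphate uptake genes passed by edgeR's quasi-likelihood test, with 3 at an unadjusted p below 0.05 and 0 called by DESeq2, the edgeR exact test and limma-voom.

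The log2 fold changes were -1.08 for CCNA_00028 (adjusted p 0.0128), -0.92 for CCNA_00138 (adjusted p 0.0021), -0.58 for CCNA_00748 (adjusted p 0.0398) and -0.66 for CCNA_00749 (adjusted p 0.0439), by edgeR's quasi-likelihood test. Adjusted over the list alone, 5 receptors were higher and 3 lower, and 2 iron uptake genes were lower. Camera called the iron list lower (median -0.27, adjusted p 9.0e-04), with an adjusted p of 0.624 with an estimated correlation. The median was -0.16 without WT replicate 1 and -0.45 without WT replicate 2, and its median difference between these libraries was 0.21. Camera did not call the receptor or phosphate lists (adjusted p 0.495 and 0.262). Both iron transport genes missed the threshold with library size scaling (adjusted p 0.177 and 0.125), with upper-quartile scaling (0.0681 and 0.0652), without ΔflaF replicate 1 (0.130 and 0.239) and without ΔflaF replicate 2 (0.103 and 0.561). They also missed it with the filter at a CPM of 10 (0.0522 and 0.0539), and CCNA_00748 with limma-voom (0.0528). With the edgeR exact test 8 receptors passed. Without WT replicate 2 the medians were -0.0036 for receptors and -0.28 for phosphate uptake genes. Without WT replicate 1 they were 0.077 and 0.011.

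Among stress and maintenance genes, dnaE2, an error-prone DNA polymerase, rose from 50.4 ± 7.56 to 80.8 ± 2.03 CPM (SD, n = 2 each), 1 of 11 SOS repair genes. The toxin-antitoxin pair parE-1 and parD-1 fell, 2 of 31 genes in that list, from 75.1 ± 17.6 to 40.9 ± 0.147 CPM and from 37.8 ± 5.77 to 21.1 ± 3.23 CPM. None of the 16 heat shock, 15 oxidative stress, 16 c-di-GMP, 19 mobile element, 23 respiration and 57 ribosomal protein genes passed by edgeR's quasi-likelihood test, with 1, 6, 1, 5, 2 and 22 of them at an unadjusted p below 0.05. DESeq2 and the edgeR exact test called 3 ribosomal protein genes each and limma-voom 0, the exact test called 2 oxidative stress genes, and these 3 tools called 0 in the other lists named. Of the ribosomal protein genes, 56 had a negative log2 fold change, with a median of -0.40, and their median difference between WT replicates 1 and 2 was 0.42.

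The log2 fold changes were 0.68 for dnaE2 (adjusted p 0.0263), -0.87 for parE-1 (adjusted p 0.025) and -0.83 for parD-1 (adjusted p 0.0331), by edgeR's quasi-likelihood test. Adjusted over the list alone, 3 SOS genes were higher, 2 toxin-antitoxin genes were lower, and 1 oxidative stress gene was higher and 1 lower. Camera called the SOS (median 0.25, adjusted p 0.0033) and mobile element lists (median 0.29, adjusted p 9.0e-04) higher and the ribosomal protein (adjusted p 2.6e-15) and respiration lists (median -0.19, adjusted p 0.0013) lower. With an estimated correlation the adjusted p was 0.624 for each. The median differences between WT replicates 1 and 2 were -0.26, -0.15, 0.42 and 0.24 in these lists. Without WT replicate 1 the median was 0.15 for mobile elements and -0.10 for respiration, and without WT replicate 2 it was 0.37 for SOS and -0.33 for respiration. Camera did not call the heat shock, c-di-GMP or toxin-antitoxin lists (adjusted p 0.495 each) or the oxidative stress list (0.679), whose median was 0.04 with a camera direction of lower. Without WT replicate 1 the median of the ribosomal protein genes was -0.15, and without WT replicate 2 it was -0.64. Without WT replicate 2 the medians were 0.12 for oxidative stress, 0.12 for heat shock, 0.31 for mobile elements, 0.15 for c-di-GMP and 0.05 for toxin-antitoxin genes. Without WT replicate 1 they were -0.07, 0.02, 0.15, -0.03 and 0.11. The toxin-antitoxin median was 0.01 without ΔflaF replicate 1. The SOS median was 0.18 without WT replicate 1, and 0.31 and 0.19 without ΔflaF replicates 1 and 2. The SOS genes past the threshold were 2 with DESeq2 and 3 with the edgeR exact test. The camera call for respiration ended without ΔflaF replicate 2 (adjusted p 0.0568), and that for mobile elements with the filter at a CPM of 10 (0.0534). With library size scaling dnaE2, parE-1 and parD-1 missed the threshold (adjusted p 0.109, 0.125 and 0.171). With upper-quartile scaling parE-1 and parD-1 missed it (0.0532 and 0.0652), and parD-1 also with the filter at a CPM of 10 (0.0516) and without ΔflaF replicate 1 (0.0711).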

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

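The direction of all 62 called features was kept in the 14 settings of the gene test wherever they were tested, and 20 of them, 5 higher and 15 lower, stayed past the threshold in all 14, among them fljK, fljM, fljN, fljO, CCNA_01529, CCNA_00438, hvyA and nstA. The kept direction was nearly fixed in advance, since the groups did not overlap for any of the 62 and every setting used the same libraries. The count of 62 became 25 (10 higher, 15 lower) with library size only, 161 (95 and 66) with the edgeR exact test, 20 (4 and 16) at an adjusted p below 0.01, and 13 (2 and 11) with glmTreat. The filter at a CPM of 10 left 14 higher. In simulation 15.4% of the exact test's calls were unchanged genes, against 8.02% for the quasi-likelihood test. These shares depend on the number of genes changed in the simulation and are not error rates of the calls made here. Leaving out 1 library gave 47 to 1162 calls (20 to 531 higher, 27 to 631 lower), with up to 53 of at least 1 on the log2 scale without WT replicate 2. The lone library of a group is then assumed to vary like the other group. For flaF the log2 fold change was -0.62 with DESeq2, -0.60 with the exact test and -0.81 to -0.37 with a library left out. Of the 10 neighbours 2 to 6 passed with a library left out. No gene list passed with an estimated correlation (0 of 24) or with fry tested for a single direction (0 of 24). Fry for changes in either direction called 6, namely hook, flagellins, swarmer, S-layer and capsule, pili and holdfast (adjusted p 0.0037 to 0.0430). By camera with an estimated correlation, lists with unadjusted p-values from 0.075 (mobile elements) to 0.338 (secretion and basal body) shared an adjusted p of 0.624. The flagellins were among them, so such a miss does not decide against a list. At an adjusted p below 0.01, 20 genes were shared with the deposited table. Some uncalled neighbours of flaF changed sign. With library size only flbT, CCNA_01521 and flbA had log2 fold changes of 0.058, 0.049 and 0.11. With upper quartiles flbA had 0.024, and CCNA_01522 had -0.0065 with DESeq2 size factors and -0.0047 with DESeq2. With 1 library left out the ranges were -0.19 to 0.060 for flbT, -0.20 to 0.047 for CCNA_01521, -0.21 to 0.26 for CCNA_01522, -0.28 to 0.52 for flmH and -0.077 to 0.026 for flbA. The cause was not tested for any of these. At the present depth and group size 50% of simulated 1.5-fold changes were recovered, and neither was varied.

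The replicate numbers do not pair the libraries by design, and the correlation of their deviations across genes was 0.01. A fit with the replicate block called 197 features (117 higher, 80 lower), all 62 among them, and gave flaF -0.59 (adjusted p 3.3e-04). In the same simulation 19.6% of its calls were unchanged genes, a share that is likewise not an error rate of the calls made here.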

Other observations

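The tests of explanations in this part were all chosen after the results were seen, as were the genes CCNA_R0017, CCNA_R0176, CCNA_03092 and CCNA_00949. Several genes without a fixed list changed beside genes already named. The noncoding feature CCNA_R0017, which lies between fljM and fljN, fell (log2 fold change -2.47, edgeR's quasi-likelihood test, adjusted p 0.0017), and CCNA_R0176, next to the hook-related CCNA_02931, fell by 1.86 (adjusted p 0.0011), though it overlaps CCNA_02930 in the gene table, so its reads are uncertain. CCNA_03092, a cytochrome P450 family gene next to nstA, rose (0.72, adjusted p 0.0124), and CCNA_00949, next to sciP, fell (-0.90, adjusted p 0.0433). Without ΔflaF replicate 1 CCNA_03092 missed the threshold (adjusted p 0.0960), and CCNA_00949 missed it with library size scaling (0.172), upper-quartile scaling (0.0815), limma-voom (0.0644) and the filter at a CPM of 10 (0.0601). Of the 62 called features, 31 had an adjacent feature called in the same direction, against a mean of 1.00 and a highest count of 10 in 10000 random placements of the calls (permutation p 1e-04, the smallest they can give). This count was made after such pairs were seen. The placements treated each feature as independent of its neighbours, so the p-value measures only a departure from that. What the count comes from was not tested.

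The rise of fljL beside the fall of the other 5 flagellins may reflect the counting of reads shared between paralogs. If reads had only moved between these genes, fljL could gain no more than the others lost, yet it gained 9910 CPM against 5703 lost, a ratio of 1.74 and at least 1.45 over the 4 pairs of libraries. This argues against moved reads as the whole cause, while a share of moved reads stays open. A cis effect of the deletion on the adjacent fljL (log2 fold change 1.98) cannot be told apart from an effect of losing flaF, because no library has flaF lost or restored elsewhere.

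Reads counted in flaF in the ΔflaF libraries could come from WT cells in those cultures, from exchanged libraries or from a part of flaF left in place. Against WT cells, fljK in ΔflaF was at most 13.1% of its WT level over the pairs of libraries, below the lowest value for flaF of 54.6%. Against an exchange of 1 library of each group, the libraries of one label differed in fljK by at most 1.14-fold. An exchange of both libraries of each group goes against the lower flaF level in every setting run (edgeR's quasi-likelihood test, unadjusted p 0.0023, adjusted p 0.103). The adjusted p was 0.0341 with DESeq2 and 0.0094 with the exact test, but 0.283 with library size scaling, 0.171 with upper quartiles and 0.112 with limma-voom. Such an exchange stays open because the extent of the deletion is not known. A part of flaF left in place (log2 fold change -0.60) cannot be told apart from reads over the whole gene, since the tables hold 1 count per feature.

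The fall of hvyA, perP and sciP may come from WT replicate 1 alone or from a lower share of swarmer cells in the ΔflaF cultures. Against the former, WT replicates 1 and 2 had 208 and 211 CPM of hvyA, 107 and 105 CPM of perP and 661 and 580 CPM of sciP. The highest ΔflaF values were 92.3, 62.9 and 394 CPM. These 3 genes also stayed lower without WT replicate 1, but this does not decide, since all 62 called features did so. A lower share of swarmer cells would lower genes confined to those cells by about the same factor. The log2 fold changes of these 3 genes and pilA were unequal and spanned 0.87, from -1.23 for hvyA to -0.36 for pilA. None of them is shown here to be expressed in swarmer cells alone, so the unequal falls do not decide. A lower share of swarmer cells therefore cannot be told apart from regulation of these genes. An effect of the flaF deletion itself was not tested apart from these.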
